A study of Mus musculus with 4 samples.

How the data were processed

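RNA from total thymocytes of 2 wild-type and 2 hnRNP L knockout (KO) mice was sequenced, with 1 library per mouse. Per the labels' protocols, ribosomal RNA was depleted, the RNA was fragmented with RNase III, fragments of 150 to 300 bp were selected and amplified for 12 PCR cycles, and barcoded libraries were sequenced on the SOLiD platform with 2 samples on each of 2 slides. The labels give all 4 mice the same mixed genetic background, which lists C57BL/6, an LckCre transgene, a fluorescent reporter and CD45.1. Which mice carried Cre, which exons of Hnrnpl were deleted, which samples shared a slide and the sex of each mouse are not given in the sources used here.

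For each library the authors deposited a table of raw read counts per RefSeq transcript, together with the ratio of reads to transcript length and the RPKM value (reads scaled by transcript length and by mapped reads). Per the file headers, the authors counted primary alignments with a mapping quality of at least 10, and the RPKM values are scaled by the number of mapped reads that each header states. The ratio and RPKM columns were checked against the counts and used in no test. A deposited table per library also lists raw read counts for exon-exon junctions, each marked as known or putative and carrying a gene symbol. Per the submitters' processing notes the genome build is mm9. The aligner, its settings and the handling of strand are not given in the sources used here.

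Each transcript table held 28283 rows for 22730 gene symbols, of which 3580 had more than 1 row. Transcripts of a gene share reads, so the transcript with the highest total over the 4 libraries was kept for each symbol. Of the symbols, 21269 were matched to a current gene through their RefSeq transcript, and 2290 of these had another current symbol; symbols are printed as the files give them. The junction tables listed 1921627 junctions, 186874 of them known and 1734753 putative, and 188794 had a read in some library.

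Mapped reads per library, per the file headers, were 99782558 and 122619310 for wild-type replicates 1 and 2, and 69061265 and 75485061 for KO replicates 1 and 2. Intervals and the limits that a count of 0 allows cover counting error only, since PCR copies are not independent molecules. Where a share is given for 1 library, its interval is the exact Clopper-Pearson interval at 95%. A count of 0 is taken to allow up to 3 reads per library.

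Genes were tested with edgeR 4.0.16 in R 4.3.3, with a robust quasi-likelihood fit on the raw counts, TMM scaling, edgeR's filter on low counts by group, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are KO over wild type. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. The correlation estimated from the data ranged from -0.051 (unfolded protein and integrated stress response) to 0.85 (histones), with 0.65 for the mature list and 0.43 for the receptor list. Where members vary together that much, the preset value makes p too small. List calls with 1 library left out were made at the preset value only, and may reflect single mice. Junctions with at least 10 reads over the 4 libraries, in genes with at least 2 such junctions, were tested with edgeR's diffSpliceDGE for usage relative to the other junctions of the gene, with the Simes test per gene. An exon was tested for skipping where its 2 inclusion junctions and the junction that skips it had reads, with at least 10 reads in every library and at least 5 reads over the libraries for inclusion and for skipping. That edgeR model had a term per library and a term for inclusion in KO. Inclusion is the mean of the 2 inclusion junctions' reads over that mean plus the skipping reads. Exon lengths come from the junction coordinates. In the exon test, exon numbers come from GENCODE M21, to which 17695 of 19001 exons, or 93.1%, were matched by exon and intron lengths. For the junctions of Hnrnpl and Ptprc, exons were numbered along the known junctions in transcript order. CPM values for single genes are TMM-scaled.

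The 24 lists covered hnRNP L and its close relatives, SR proteins and core splicing regulators, double-negative, double-positive and mature single-positive thymocytes, gamma-delta and innate-like T cells, B cells, myeloid cells, erythroid cells, thymic stroma, adipose with parathyroid or lymph node tissue, T cell receptor signalling, T cell receptor activation response, chemokine and sphingosine receptors, actin cytoskeleton, integrins and adhesion, cell cycle, replication-dependent histones, p53 targets, interferon response, cytosolic ribosomal proteins, glycolysis, the unfolded protein and integrated stress response, and sex-linked genes. A further list held 30 genes for the junction test. The lists, the tests, the alternatives except the last 2 named below, and the rule for naming genes were fixed before the data were examined. The rule named Hnrnpl, up to 10 genes per direction past the threshold with a mean of at least 5 CPM and both KO libraries on the same side of both wild types (clone names left out), the 5 genes with the smallest p in a direction with fewer than 5 past it, and up to 4 members per list with the smallest p. For junctions it named Ptprc, Hnrnpl, the 10 genes with the smallest gene-level p, up to 10 exons past the threshold, and members of the junction list past the threshold adjusted over that list alone. Some of the members so chosen are summarised by their list's counts.

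The steps were tested on simulated data with features changed by known amounts. Gene counts changed 4-fold were recovered in 100 of 100 cases and 2-fold in 63 of 100, with 23 unchanged genes among 186 calls, a share above the threshold. The shifted list was the only list called. The simulated genes varied independently, so this does not cover false list calls where members vary together. Junctions changed 4-fold were recovered in 26 of 100 cases and 2-fold in 0 of 100, with 0 unchanged genes among 29 calls. Exons whose odds of inclusion changed 4-fold were recovered in 69 of 100 cases and 16-fold in 85 of 100, with 3 unchanged among 157 calls. The simulated exon counts had no variation between mice, and changes were placed only in exons with many inclusion and many skipping reads. In the data the median was 3 skipping reads per exon and library, so the exon figures are too favourable.

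The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, edgeR without robust moderation, the replicate number as a block, each library left out in turn, camera with an estimated correlation, fry, limma-voom diffSplice, other read minimums for junctions and exons, and other counts of inclusion. The last 2 alternatives, added after seeing the data, left out small RNA genes with their host genes and removed each library's trend with transcript length. Groups of 2 were too small for a test of single outlying libraries or of other splits of the samples, and the smallest p of a permutation of 2 against 2 is 0.333.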

Results

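The thymus makes T cells, and total thymocytes hold these developing cells at all their stages. The libraries came from thymocytes of 2 wild-type and 2 hnRNP L KO mice. hnRNP L, the product of Hnrnpl, is an RNA-binding protein that regulates the splicing of pre-mRNA. Reads assigned to 1 transcript per gene numbered 41775795 and 51544714 in wild-type replicates 1 and 2, and 27548708 and 28677506 in KO replicates 1 and 2. Junction reads numbered 4759678 and 6146421 in the wild types, and 3302915 and 3515308 in the KOs. Across genes, which are not independent replicates, log2 CPM (reads scaled to library size) correlated at 0.987 between the wild types and at 0.983 between the KOs. The correlation of wild-type replicate 2 with KO replicate 1 was 0.987 as well. KO replicate 1 had 4116 reads of the Y-linked gene Ddx3y, against 17, 1 and 1 in wild-type replicate 1, wild-type replicate 2 and KO replicate 2, and 222 reads of Xist, the RNA of the inactive X chromosome, against 57852, 85249 and 87390. By these reads KO replicate 1 came from a male and the other libraries from females, so the KO mice differ in sex. Small RNA genes and their host genes took 8.10% of the gene reads of wild-type replicate 1 (95% interval 8.09 to 8.10%), against 1.40% (1.40 to 1.40%), 2.09% (2.09 to 2.10%) and 1.08% (1.07 to 1.08%) in wild-type replicate 2, KO replicate 1 and KO replicate 2.

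The comparison of KO with wild type asks first how far the targeted gene itself was reduced. Hnrnpl (NM_177301, mm9 chromosome 7, 29595909 to 29607285) was lower in both KO libraries than in both wild types, and it was not absent from either. It had 854 and 813 CPM in the wild types (834 ± 29.3, SD, n = 2) and 467 and 208 in KO replicates 1 and 2 (338 ± 183, SD, n = 2). KO replicate 1 thus held 56.0% of the wild-type mean and KO replicate 2 held 25.001%. Its known junctions from exon 1 to exon 7 stood at 56.2% and 17.8% of the pooled wild types, and those from exon 7 to exon 13 at 60.8% and 28.5%. The log2 fold change was -1.30 (SE 0.42), which did not pass the edgeR test over all genes (adjusted p = 0.486). Without KO replicate 1 it was -2.01 and passed (adjusted p = 0.0041), and without KO replicate 2 it was -0.84 (adjusted p = 0.113).

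**Figure D1:**
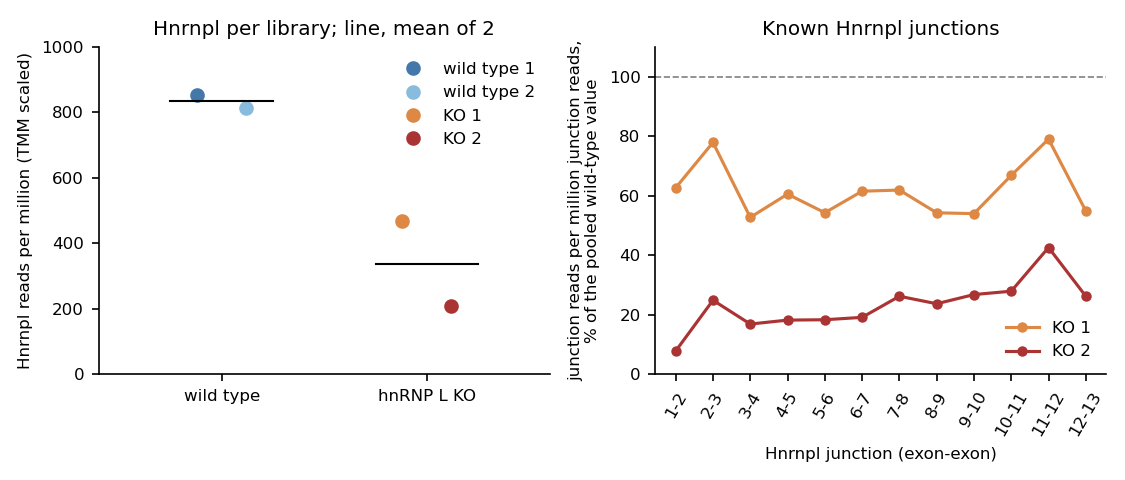
Left, Hnrnpl CPM (TMM-scaled) for each library, with a line at the mean of 2; the wild types lie at 854 and 813 and the KOs at 467 and 208. Right, reads of each known Hnrnpl junction, scaled to the library's junction reads, as a percentage of the pooled wild types (dashed line at 100), for each KO library.

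Which other genes changed was asked over 13733 tested genes. The only gene past the threshold was Gh, which encodes growth hormone (NM_008117, mm9 chromosome 11, 106161582 to 106163124), and it rose in KO. It had 2 and 3 reads in the wild types and 186 and 466 in the KOs, a ratio of summed reads over library totals, without TMM scaling, of 216 (95% counting interval 92.3 to 669), and a log2 fold change of 7.53 (SE 0.58, adjusted p = 0.0364). Known Gh junctions, whose reads were counted separately, held 1 read in KO, against 93.8 at the median rate of 105 genes of like length with as many known junctions. The next genes on the higher side did not pass. They were Smyd1, a methyltransferase gene (log2 fold change 1.36, SE 0.16, adjusted p = 0.113), Syt11, a synaptotagmin (1.29, SE 0.19), Atxn1 (0.87, SE 0.13) and Fhl4, a LIM-domain gene (1.48, SE 0.22). On the lower side none passed: Hist1h4j, a histone H4 gene, had -2.11 (SE 0.21, adjusted p = 0.0759), Fzd10, a Wnt receptor, -1.81 (SE 0.24), Hist1h2an -0.99 (SE 0.14), Hist1h2ao_dup1 -0.79 (SE 0.11) and Pfkl, a phosphofructokinase of glycolysis, -0.79 (SE 0.11).

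By edgeR 1 gene was thus higher in KO and 0 were lower, while 1360 genes had an unadjusted p under 0.05 (864 higher, 496 lower), against 687 by chance. DESeq2 called 103 genes (62 higher, 41 lower) and limma-voom 0, and with no filter on low counts edgeR called 62 (44 higher, 18 lower). The count was 2 without wild-type replicate 1, where Gh no longer passed (adjusted p = 0.170), 43 without wild-type replicate 2, 427 without KO replicate 1 and 13 without KO replicate 2, where the lone library of a group is assumed to vary like the other group. Gh also missed the threshold under upper-quartile scaling (adjusted p = 0.0793), without robust moderation (0.188) and with limma-voom (0.303).

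Of the 24 gene lists, those of replication-dependent histones, of mature T cells and of chemokine and sphingosine receptors fell. All 22 tested replication-dependent histone genes, which supply the histones of newly made DNA, had a negative fold change, with a median log2 fold change of -0.81. Of these, 0 passed over all genes and 4 were lower when adjusted over the list alone: Hist1h2ae (-0.88, SE 0.14), Hist1h2ab (-0.56, SE 0.14), Hist2h2ac (-0.84, SE 0.21) and Hist1h4a (-1.45, SE 0.37). The camera test called the list (adjusted p = 4.2e-14), but not with an estimated correlation (p = 0.180, adjusted p = 0.910). Wild-type replicate 1, with its larger share of small RNA reads, weighed on this list: the median was -0.39 without it.

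The list of mature single-positive and egress genes, which mark T cells about to leave the thymus, fell in the camera test (adjusted p = 0.0299), with 21 of 26 members negative and a median of -0.25. With an estimated correlation its p was 0.508 (adjusted p = 0.910). Its members with the smallest p went both ways: H2-K1, an MHC class I gene, had -0.61 (SE 0.25) and Cd2, an adhesion receptor, -0.51 (SE 0.23), while Itga4, an integrin, had 0.41 (SE 0.14) and Runx3, a transcription factor of CD8 T cells, 0.40 (SE 0.15). The chemokine and sphingosine receptor list, which steers thymocytes through and out of the thymus and shares 3 members with the list before (Ccr4, Ccr7 and S1pr1), fell as well (adjusted p = 0.0299, 13 of 16 members negative, median -0.29). With an estimated correlation its p was 0.373 (adjusted p = 0.910). Ccr9, the receptor for the thymic chemokine Ccl25, had -0.68 (SE 0.27), Ccr8 -0.69 (SE 0.19) and Cxcr4 -0.42 (SE 0.15). None of the members of either list passed over all genes or adjusted over the list alone.

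Both of these lists rested on KO replicate 2. Without it neither list was called, at medians of 0.06 and -0.02, and without KO replicate 1 the medians were -0.65 and -0.59. The stroma and epithelium list was called up in the fit without KO replicate 1 (median 0.55) and down without KO replicate 2 (-0.51). The mature list also missed the threshold without wild-type replicate 2 (adjusted p = 0.126) and with the length trend removed (0.0563), and the receptor list without wild-type replicate 1 (0.0634), without wild-type replicate 2 (0.177) and with no filter on low counts (0.0621). Fry called 0 of the 24 lists (adjusted p = 0.799 for each of these 3 lists), and 3 lists were called by camera in all 4 libraries, against 4 without wild-type replicate 1, 1 without wild-type replicate 2, 9 without KO replicate 1 and 9 without KO replicate 2.

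**Figure D2:**
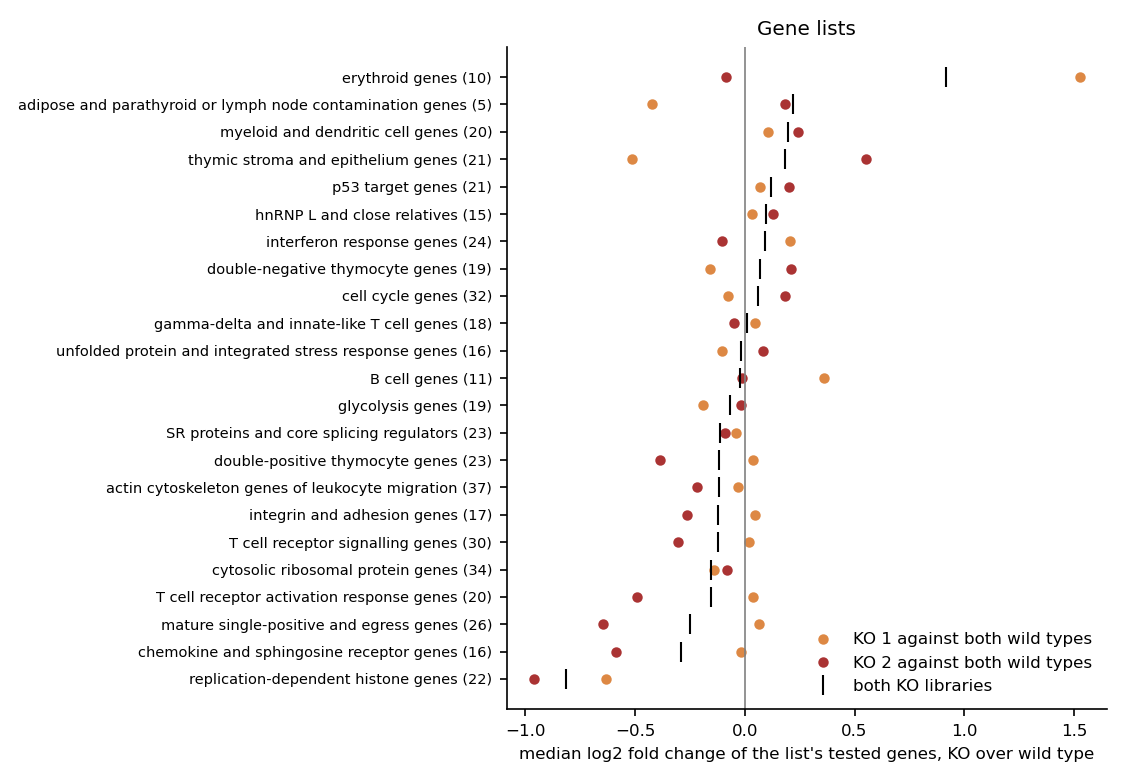
Median log2 fold change (KO over wild type) of each gene list with the number of tested genes in brackets, for both KO libraries (bars) and for each KO library against both wild types (points); the sex-linked list is not drawn. The histone list has a median of -0.81, and the mature and receptor lists lie lower in KO replicate 2 (-0.65 and -0.59) than in KO replicate 1 (0.06 and -0.02).

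The other 21 lists were not called. Among thymocyte stages, the double-positive list, of cells that carry both CD4 and CD8, had a median of -0.12 (adjusted p = 0.162), or -0.38 without KO replicate 1, where it was called (7.2e-04), and Rag2, a subunit of the recombinase that rearranges the T cell receptor genes, was its only member to pass adjusted over the list alone, at 340 and 335 CPM in the wild types and 491 and 570 in the KOs (0.65, SE 0.14). The double-negative list, of the earliest stage, had a median of 0.07 and a mean of 0.03 while its test pointed down (adjusted p = 0.883). Dtx1, a Notch target, had -0.64 (SE 0.22) and Gata3 0.24 (SE 0.12). For gamma-delta and innate-like T cells the median was 0.01 (adjusted p = 0.908), and Zbtb16, the transcription factor of innate-like T cells, had -1.17 (SE 0.30).

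Markers of other cell types gave medians of -0.02 for B cells (mean 0.13, test upward, adjusted p = 0.504), 0.20 for myeloid cells (0.178) and 0.92 for erythroid cells (0.0977). The erythroid genes were higher in KO replicate 1: without KO replicate 2 the median was 1.53, and without KO replicate 1 it was -0.09. Alas2, the first enzyme of heme synthesis in red cells, had 27.3 and 27.0 CPM in the wild types and 118 and 23.6 in KO replicates 1 and 2. The stroma and epithelium list, at 0.18 (adjusted p = 0.714), had medians of -0.51 for KO replicate 1 and 0.55 for KO replicate 2. Epcam, an epithelial adhesion gene, had 0.82 (SE 0.23). The adipose, parathyroid and lymph node list had a median of 0.22 and a mean of -0.09, and its test pointed down (adjusted p = 0.883). The sex-linked list had a median of 7.87 (adjusted p = 0.323) through KO replicate 1 alone, the library with Y-linked reads.

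The medians of the lists of T cell function were lower in KO replicate 2 than in KO replicate 1. The T cell receptor signalling list had a median of -0.12 (adjusted p = 0.223), in which Cd3e, a chain of the receptor complex, had 0.97 (SE 0.29) and Cd247, another chain, -0.47 (SE 0.20). The list of genes that respond to receptor activation had -0.16 (adjusted p = 0.0713), with Dusp2 at -0.51 (SE 0.16) and Junb at -0.39 (SE 0.16). The actin cytoskeleton list had -0.12 (0.180), with Ezr, which links actin to the membrane, at 0.58 (SE 0.18), and the integrin and adhesion list -0.12 (0.302), with Icam2 at -0.51 (SE 0.17). Without KO replicate 1 camera called all 4 of them, at medians of -0.31 (adjusted p = 0.0060), -0.49 (1.1e-04), -0.22 (0.00996) and -0.26 (0.0167), and without KO replicate 2 the medians were 0.019, 0.036, -0.029 and 0.047 (adjusted p at least 0.572).

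For splicing factors, the hnRNP list had a median of 0.10 (adjusted p = 0.754), with Hnrnpa2b1 at 0.38 (SE 0.14), and the SR protein list -0.11 (0.0977), with Srsf10 at -0.40 (SE 0.10) and Tra2a at -0.37 (SE 0.11). The cell cycle list had 0.06 (0.703), with Mcm4, a subunit of the replicative helicase, at 0.33 (SE 0.15). The p53 target list had 0.12 (0.278). In it Cdkn1a, an inhibitor of the cell cycle, had 1.01 (SE 0.35), or 1.45 without KO replicate 1 and 0.35 without KO replicate 2. The interferon list had 0.09 (0.323) and the ribosomal protein list -0.15 (0.0519), with Rpl32 at -0.44 (SE 0.13). The glycolysis list had -0.07 (0.154), and Pfkl was its only member to pass adjusted over the list alone. The unfolded protein and integrated stress response list had -0.02 (0.714).

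Leaving out 1 library brought further calls among these lists, at the preset correlation. Among the lists called without KO replicate 2 were the erythroid list, higher at a median of 1.53, and the stroma and epithelium list, lower at -0.51. Without KO replicate 2 the interferon list was called up (median 0.21, adjusted p = 7.3e-05), against -0.10 without KO replicate 1, and the B cell list was called up (0.36, 0.0207), as was the sex-linked list (8.88, 0.0112). The ribosomal protein (-0.14, 0.0027), glycolysis (-0.19, 0.0245) and double-negative (-0.16, 0.0426) lists were called down there. Without wild-type replicate 1 the SR protein (-0.11, 0.0382) and adipose (-0.35, 0.0382) lists were called down. The ribosomal protein list also passed without small RNA genes (0.0239) and without robust moderation (0.0489), and the erythroid list without robust moderation (0.0412).

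The series asks about alternative splicing under hnRNP L, which junction reads address. Of 95139 tested junctions in 9475 genes, 4 junctions in 4 genes were used more in KO. Cd8b1, the beta chain of the CD8 coreceptor, had more reads in KO on a putative junction on chromosome 6 (71272893 to 71279691) that skips its exon 2 of 363 nt, with 6 and 6 reads in the wild types and 14 and 73 in the KOs (log2 change in relative usage 2.60, adjusted p = 0.0041). Dpp4, the surface peptidase CD26, had more on a putative junction on chromosome 2 (62203120 to 62212423) that skips its exon 10 of 113 nt, with 0 and 0 reads against 13 and 15 (adjusted p = 0.0047). Diap1, a formin that builds actin filaments, had more reads on a known junction on chromosome 18 (38015606 to 38015828), 19 and 21 against 74 and 51 (1.53, adjusted p = 0.0047). In Ptprc, which encodes the phosphatase CD45, the known junction of exon 4 with exon 5 on chromosome 1 (140016743 to 140019033) rose from 0 and 6 reads to 13 and 31 (2.46, adjusted p = 0.0050).

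The gene-level test called the same 4 genes, with adjusted p of 0.0033 for Cd8b1, 0.0117 for Dpp4, 0.0117 for Diap1 and 0.0206 for Ptprc. The next genes by p, Fgfr1op2, Cep72, Abcf3, Sept6, 9430015G10Rik and Neb, did not pass (adjusted p at least 0.639 for their junctions). An unadjusted p under 0.05 was reached by 2423 junctions, against 4757 by chance. Limma-voom called 1 junction, that of Diap1, and 0 genes. The calls were 7 without wild-type replicate 1 and 9 without KO replicate 2, with Diap1 alone kept in each, 10 without wild-type replicate 2, with Ptprc alone kept, and 3 without KO replicate 1, with Cd8b1 and Ptprc kept.

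**Figure D3:**
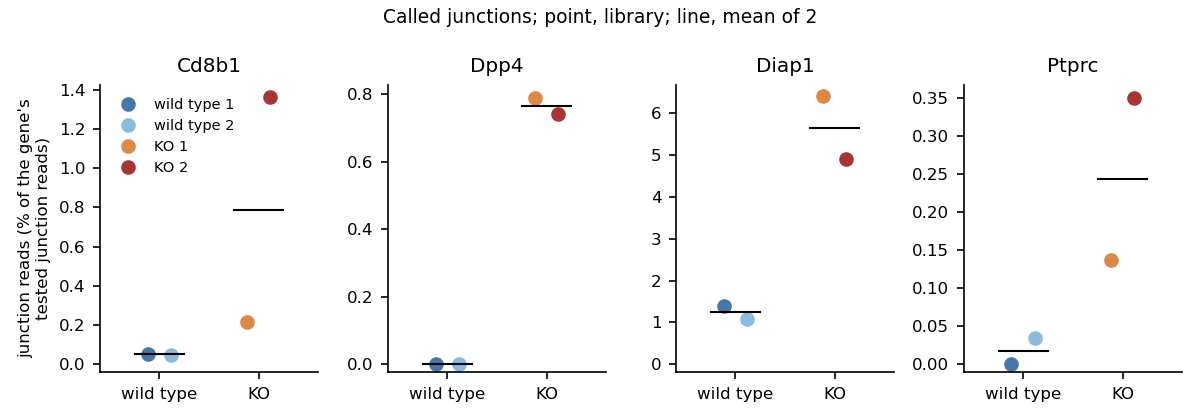
Reads of the 4 called junctions as a percentage of the tested junction reads of their gene, for each library, with a line at the mean of 2. Each KO library lies above both wild types for each of the 4 junctions.

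CD45 is made in several forms that differ by the variable exons 4, 5 and 6 of Ptprc, and their skipping is a textbook function of hnRNP L in T cells. Exon 4 (mm9 chromosome 1, 140019033 to 140019161, 129 nt) was included at 0.395% and 2.90% in the wild types (1.65 ± 1.77%, SD, n = 2) and at 14% and 19.8% in the KOs (16.9 ± 4.12%, SD, n = 2), a difference of 15.3 points and larger than the spread between replicates. In the exon test, which sets the junctions of exon 4 with exons 3 and 7 against that of exon 3 with exon 7, it was included at 0.455 ± 0.643% (SD, n = 2) and 10.3 ± 1.19% (SD, n = 2), 9.82 points apart, and did not pass (adjusted p = 0.493). Exon 6 (140014331 to 140014471, 141 nt) was included at 6.66 ± 0.910% (SD, n = 2) in the wild types and at 14.3 ± 2.83% (SD, n = 2) in the KOs, 7.60 points apart. Exon 5 (140016597 to 140016743, 147 nt) was included at 35.2 ± 2.36% (SD, n = 2) and 36.6 ± 10.3% (SD, n = 2), a difference of 1.37 points that lay within the spread.

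Among 483 tested junctions in 29 genes of the splicing list, 3 passed adjusted over the list alone, and all 3 were in Ptprc: exon 4 with exon 5 (adjusted p = 1.0e-04), exon 3 with exon 4 (0.0036) and exon 6 with exon 7 (0.0343). Only the first passed over all junctions. By the junction upstream of exon 4 alone, the share was 0 of 126 and 0 of 134 reads in the wild types, which allow up to 2.38% and 2.24%, and 7.53% (exact 95% interval 3.08 to 14.9%) and 7.92% (3.48 to 15.0%) in the KOs. The change at exon 6 came from its downstream junction: by the upstream junction alone the difference was 0.944 points, and by the downstream one 12.95 points. For exon 4 these were 7.72 and 21.1 points, and for exon 5 they turned from 10.3 to -4.89 points.

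**Figure D4:**
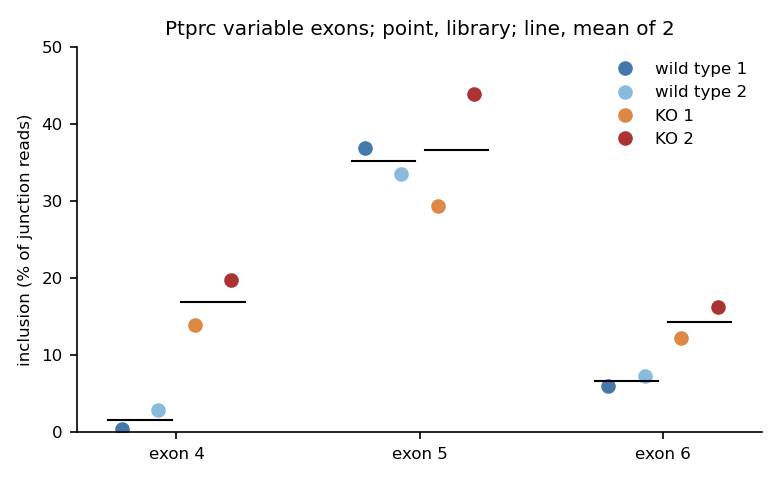
Inclusion of Ptprc exons 4, 5 and 6 as a percentage of junction reads, for each library, with a line at the mean of 2. For exons 4 and 6 both KO libraries lie above both wild types, and for exon 5 they lie on either side.

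Whether whole exons were skipped or included more was asked for 3293 exons. None passed the edgeR test, and the smallest adjusted p, 0.0614, belonged to the same exons of Dpp4 and Cd8b1 that the junction test found. Dpp4 exon 10 was included at 100% in the wild types, with 0 skipping reads that allow up to 1.596% and 1.653%, and at 88.8 ± 0.309% (SD, n = 2) in the KOs. Cd8b1 exon 2 was included at 99.7 ± 0.000958% (SD, n = 2) and at 95.1 ± 5.003% (SD, n = 2), with the 73 skipping reads of KO replicate 2 making up most of the difference. Exon 5 of Fgfr1op2 had 62.1 ± 12.2% and 91.0 ± 3.61% (SD, n = 2 each) without passing.

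By an unadjusted p under 0.05, 191 exons differed (99 more included, 92 more skipped), against 165 by chance. Inclusion differed by at least 10 points with no overlap between the groups for 440 exons. Of these, 270 were more included in KO. The counts were 361 and 288 for the other 2 ways to part the 4 libraries into pairs. With at least 5 reads per library in place of 10, or with the smaller inclusion junction in place of both, 2 exons passed, those of Dpp4 and Cd8b1. Median depth was 73 reads per exon and library, with 3 skipping reads.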

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

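No test was run on this result, which was picked out after its reads were seen. A putative Hnrnpl junction from exon 1 to exon 7 (mm9 chromosome 7, 29596187 to 29603480), which leaves out exons 2 to 6, had 7 reads in the KO libraries, 2 in replicate 1 and 5 in replicate 2. It had 0 reads in each wild type, which allows up to 3 reads per library. It stood out because it lies outside the tested data, under the minimum of 10 reads, and was seen in KO alone.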

How the results depend on the processing

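Leaving out small RNA genes and removing the length trend were tests chosen only after the results were seen. Hnrnpl was negative under every alternative run, from -2.01 to -0.84 with 1 library left out, and passed only without KO replicate 1. Of 1423 alternative values of the 102 other named genes, 1411 kept their direction, 68 passed where the reported value did not, and 4, all of Gh, no longer passed. With 1 library left out, where a lone library is assumed to vary like the other group, the genes called ranged from 2 to 427 (higher, 1 to 200; lower, 1 to 227), the lists from 1 to 9, the junctions from 3 to 10, the genes with a junction called from 3 to 9, and the exons stayed at 0. With upper-quartile scaling, limma-voom and no robust moderation, 0 genes were called, 0 of them higher, and without robust moderation 5 lists. With no filter on low counts 62 genes were called (44 higher, 18 lower), of 19743 tested, by DESeq2 103 (62 higher, 41 lower), and without small RNA genes 3 (2 higher, 1 lower). Camera with an estimated correlation and fry called 0 lists. Limma-voom diffSplice called 1 junction and 0 genes. With at least 5 reads per library, and with the smaller inclusion junction, 2 exons passed, all 2 more skipped. The replicate number used as a block gave 121 genes (52 higher, 69 lower), 5 lists (the 3 reported, T cell receptor activation response, adjusted p = 0.0274, and sex-linked), 10 junctions, 6 genes by the gene-level junction test and 0 exons. The numbers are not stated to pair mice, and deviations of same-numbered libraries correlated at 0.259 across genes. RLE scaling, the stricter filter and the removed length trend each left 1 gene called. Apart from the numbers of genes tested and libraries used, the cause was not tested.

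In points of inclusion, Ptprc exon 4 differed by 7.72 by its upstream junction and 21.1 by its downstream one (12.4 to 18.2 with 1 library left out), exon 5 by 10.3 upstream (-5.89 to 8.64), and exon 6 by 0.944 and 12.95 (5.61 to 9.60). The cause was not tested. With 1 library left out the direction turned for the mature single-positive list (median -0.65 to 0.063), for the medians of 14 of the 21 lists not called, such as the double-positive (-0.38 to 0.038) and cell cycle (-0.078 to 0.19) lists, and for 11 named genes, none of which had passed. Their log2 fold changes ranged from -0.21 to 2.12 for Alas2, -0.29 to 1.91 for Hba-a1_dup1, -0.45 to 0.82 for Adipoq, -0.44 to 0.28 for Cr2, -0.67 to 0.065 for Dcn, -0.061 to 1.10 for Foxn1, -0.29 to 0.024 for Herpud1, -2.62 to 11.66 for Ddx3y, -1.41 to 10.95 for Eif2s3y, -2.89 to 9.51 for Uty and -3.20 to 9.96 for Kdm5d. The last 4 are Y-linked and turned without KO replicate 1, the library that holds their reads. With this number of mice, simulated 2-fold changes of 100 junctions, all well above the read minimum, were recovered for 0, and 4-fold ones for 26.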

Other observations

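The tests weighed here for growth hormone, for the histones and for the mature and receptor lists were chosen only after the results were seen, and so were the accounts of single KO libraries. KO replicate 2, the library with less Hnrnpl, had 427 genes past the edgeR threshold against both wild types (200 higher, 227 lower), with the lone library assumed to vary like the wild types. Genes of mature and migrating T cells fell in it: 12 members of the mature list and 5 of the receptor list passed, among them Ccr9 (log2 fold change -1.18, SE 0.12), Ms4a4b (-1.13, SE 0.13), H2-K1 (-1.04, SE 0.13), the activation marker Cd69 (-1.005, SE 0.13), the egress receptor S1pr1 (-0.98, SE 0.13), the lymph node homing receptor Ccr7 (-0.88, SE 0.14) and Zbtb7b, which directs the CD4 lineage (-0.86, SE 0.14). Rag2 (0.75, SE 0.11) and the cell cycle inhibitor Cdkn1a (1.45, SE 0.19) rose in it, as did the thymic epithelial genes Epcam (1.10, SE 0.17), Krt18 (1.06, SE 0.16) and Ccl25 (1.10, SE 0.18). Of the gamma-delta and innate-like genes, Sox13 (1.02, SE 0.15) rose and Zbtb16 (-1.63, SE 0.26) fell. Whether the KO libraries differ from each other was not tested.

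Among the genes called higher in KO replicate 1 against both wild types were many red cell genes: Alas2 (2.12, SE 0.11) and the globins Hba-a1_dup1 (1.91, SE 0.14), Hbb-b1 (1.64, SE 0.14) and Hbb-b2 (1.66, SE 0.13). Gh (6.84, SE 0.38) and Gm14085 (2.17, SE 0.24) rose more than these. The genes called there count some reads more than once, since Hba-a1_dup1 and Hba-a2_dup1 hold the same reads, and so do Hba-a1_dup2 and Hba-a2_dup2. Hist1h4j (-1.88, SE 0.20) fell. Xist (-7.62, SE 0.19) fell too, which goes with the sex of this mouse, male by its reads. Sex and genotype cannot be told apart in this comparison. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in wild-type replicate 1 stood at 0.272%, 0.366%, 0.463% and 0.360% of their level in KO replicate 1.

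Growth hormone reads rose in both KO libraries, at 186 and 466 reads against 2 and 3. Pituitary tissue is argued against, since the reads of 6 other pituitary genes in KO came to 0.460% of the Gh reads. Spliced mouse Gh transcripts are argued against as well: known Gh junctions held 0.153 reads per 100 Gh reads, under the 5th percentile of 4.24 for 105 genes of like length with as many known junctions. A candidate explanation that stays open is reads from an unspliced or foreign copy of a growth hormone gene, such as a segment in a Cre transgene, although the labels list LckCre for all 4 mice; no transgene sequence was tested. No test addressed a direct effect of hnRNP L on Gh either.

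The histone list was lower in KO, at a median of -0.81 over 22 genes. With the trend with transcript length removed, the median was -0.64 (camera adjusted p = 1.3e-11). That trend was smoothed over genes of all lengths and may miss a steep fall among the shortest. The test thus cannot exclude length as the cause. Without wild-type replicate 1, the library with more small RNA reads, the median was -0.39. This argues against that library as the whole cause. That fit rests on a single wild-type library, and the cut-off for this reading, set after the value was seen, was looser than that for length. Both steps brought the median closer to 0. The 14 DNA replication genes had a median of 0.094 (quartiles 0.04 and 0.13). This argues against fewer cells in S phase only so far as the RNA of these genes tracks the share of such cells, which was not tested. Genes under 150 nt had a median of -2.08 and those of 300 to 500 nt -0.30. The genes of 300 to 500 nt include histone genes such as Hist1h4j, so their median is in part the fall of the histones themselves. How far each library kept short RNA may still add to the histone values. An effect of hnRNP L loss on histone RNA was not tested and stays open as a hypothesis, and the call itself was lost with an estimated correlation (p = 0.180).

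The mature and receptor lists were lower through KO replicate 2. Over all 4 libraries the mature list's median was -0.25 with and without the trend with length, and the receptor list's was -0.29 and -0.28. This argues against that trend for these medians only, since KO replicate 2 alone was not fitted with the trend removed. The mature list's camera adjusted p went from 0.0299 to 0.0563 when the trend was removed. With an estimated correlation camera called neither list (adjusted p = 0.910 for each), and fry called neither (adjusted p = 0.799 for each). Fewer T cells in that sample cannot be told apart from fewer mature cells: without KO replicate 1 the double-positive list had a median of -0.38 and the T cell receptor signalling list -0.31, against -0.65 for the mature list (quartiles -0.91 and -0.32), with the signalling list just above that upper quartile. The stroma and epithelium list was called up in that fit (0.55, quartiles 0.19 and 0.94), but down without KO replicate 2 (-0.51). The B cell, myeloid and erythroid lists, at -0.012, 0.24 and -0.088 without KO replicate 1, were not called. Their quartiles overlap those of the stroma and epithelium list. A stronger loss of hnRNP L in KO replicate 2 may bear on the lower mature and receptor lists and was not tested. By their reads the KO mice also differ in sex, which cannot be told apart from Hnrnpl level in a contrast of the KO replicates.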
